A study of Homo sapiens with 4 samples.

How the data were processed

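Total RNA from GFP-positive and GFP-negative MDA-MB453 cells was amplified to biotin-labelled cRNA and hybridised to Illumina bead arrays, per the labels' protocols. What drives the GFP marker is not given in the sources used here. Samples were grouped by their titles and the GFP label, with 2 arrays in each of 2 groups. The deposited intensity values are bead signals per probe, not normalized per the file headers, on a linear scale. GenomeStudio 2009.2 is named in the submitters' processing notes, and whether it subtracted background is not given in the sources used here. The deposited table also holds a detection p-value for each probe and array, which moves in steps of 1 in 770 and ranks the probe among the negative controls. A separate deposited table holds log2 values. Compared with the signals, its columns were the log2 signals after quantile normalization, to within 0.00033, with a median of 7.53 on every array. It is not centred per gene, higher values are brighter, and no label states its normalization.

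Median signals were 178 and 192 on the GFP-positive arrays and 185 and 184 on the GFP-negative arrays. Between 36.8% and 38.5% of probes per array had a detection p under 0.05. The median signal lies near background, so differences of dim genes are compressed, and the number of arrays limits precision.

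Signals were processed in R 4.3.3 with limma 3.58.1. The neqc function corrected background by normexp, with the background inferred from the detection p-values because no control probe signals were used here, added an offset of 16, quantile-normalized the arrays and took log2. Probes with a detection p under 0.05 on both arrays of at least 1 group were tested, 18098 in all. Group differences were fitted with lmFit and eBayes (2 residual and 5.31 prior degrees of freedom), and 2-sided p-values were adjusted by Benjamini-Hochberg over tested probes with a threshold of 0.05. An exact permutation test of 2 against 2 cannot give a 2-sided p below 0.333, so the calls rest on limma's pooled variance. Non-overlapping groups were seen for 72.6% of tested probes. The chance level of 33.3% holds for unfiltered probes only. Requiring detection on both arrays of 1 group raises the share by itself, so the excess cannot be read from these values. The labels do not say whether the arrays of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

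A probe detected on neither array of a group has only a bound there. Its fold is given as "at least N-fold", the brighter group's mean against the dimmer group's mean of, per array, the higher of the probe's own value and the lowest normalized log2 value of a detected probe (6.11 and 6.17 on the GFP-positive arrays, 6.15 and 6.09 on the GFP-negative arrays). The same bound is given for named genes detected on 1 of the 2 arrays of the dimmer group, a choice made after the data were examined. Other differences are given as log2 fold changes, GFP-positive minus GFP-negative, ± SE, and group means of log2 signal ± SD (n = 2).

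Probes were named from the platform annotation given for the array. Of all probes, 30111 had 1 gene symbol, 8 had several and were not named, and 17202 were unnamed here. Symbols of 30072 probes were updated through gene identifiers to the GRCh38.p14 gene table, and others kept the annotation's name. A gene counts as called where at least 1 of its probes is. For gene lists, a gene is represented by its brightest tested probe. Several genes of the lists had no named probe and are not analysed here.

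Choices made before the data were examined were the groups, the tests, 36 gene lists and the naming rule. The rule takes the 15 genes with the largest called fold change in each direction among probes whose groups do not overlap, up to 4 members of each list past the threshold with the largest change (or up to 2 as values where none passes), and a set of stem cell, epithelial and receptor genes. Lists were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg over lists of at least 5 tested members, and again with an estimated correlation and with fry. Hedgehog, endothelial and erythroid lists had fewer members and were given as values. With an estimated correlation, camera takes its degrees of freedom from the residuals, 2 here, so it has little power to call any list. Another 10 lists were written after a first look at the data, for intestinal, germline, Müllerian, imprinted, melanocyte, liver, prostate, lung, squamous and kidney genes.

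The series text describes pairs of GFP-positive and GFP-negative RNA isolated on different days, so the replicate number was taken to mark a shared day. The deviations of same-numbered arrays from their group means correlated at 0.219 across probes. The main comparison has no block, and a fit with the replicate number as a block was run as an alternative. In that fit 0 probes passed for the replicate number itself (limma), and 1832 had an unadjusted p under 0.05. The same text says that RNA batches were combined before hybridisation, and how this relates to the arrays is not clear from the labels.

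Alternatives were no background correction, scaling to the 75th percentile, cyclic loess, an offset of 50, no detection filter, only probes with a detection p under 0.01 on all arrays, the deposited log2 table, the replicate block, an intensity trend with robust variances, and leaving out each array in turn, where the lone array is assumed to vary like the other group. For lists, the mean over a gene's probes was also used. The procedure was tested on simulated values for the 18098 probes of this comparison: of 50 probes changed at each size, 5, 32, 50 and 50 were recovered at 1.5-, 2-, 4- and 8-fold, with 8 false calls. Far fewer probes were changed there than were called in the data. The adjusted threshold depends on that share, so these rates do not carry over directly. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.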

Results

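Gene expression was measured with bead arrays in MDA-MB453, an established human breast cancer cell line, separated by a green fluorescent protein (GFP) marker. The GFP-positive cells are named cancer stem-like cells in the labels and the GFP-negative cells are their counterpart without that property. Each group had 2 arrays, 4 in all. The number of probes detected above the negative controls was 18015 and 17400 in GFP-positive replicates 1 and 2, and 17595 and 18197 in GFP-negative replicates 1 and 2. With 2 arrays per group, the number of arrays limits the precision of every value. Across the 18098 tested probes, Pearson's r was 0.991 between the GFP-positive arrays and 0.987 between the GFP-negative arrays, and lay between 0.843 and 0.856 for arrays of different groups (correlations across probes, which are not independent replicates). No probe had an identical signal on any pair of arrays.

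The comparison asks how the stem-like fraction of the line differs from the rest in gene expression. GFP-positive cells had far more signal for ALDH1A3, an aldehyde dehydrogenase that makes retinoic acid, and for CD44, the hyaluronan receptor used as a stem cell surface marker. ALDH1A3 was at least 286-fold higher (log2 signal 14.28 ± 0.36 against 5.10 ± 0.11, SD, n = 2) and CD44 at least 248-fold higher (14.08 ± 0.13 against 4.90 ± 0.02). The other tested CD44 probes were at least 35.6- and 1.6-fold higher. HAS3, which synthesises hyaluronan, was at least 126-fold higher. GFP-negative cells had far more signal for NTS, the precursor of the peptide neurotensin, which was at least 514-fold lower in GFP-positive cells (5.43 ± 0.23 against 15.15 ± 0.09), while its receptor NTSR1 was at least 95.5-fold higher there (12.70 ± 0.17 against 4.99 ± 0.06). Adjusted p was 3.57e-07 for ALDH1A3 and NTSR1 and 3.26e-07 for CD44 and NTS (limma moderated test, Benjamini-Hochberg).

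Among the other genes with the largest differences upwards were the cadherin-family gene FAT1 (at least 213-fold), the adipogenesis-related ADIRF (at least 156-fold), the stress-responsive cytokine GDF15 (at least 166-fold), the glycolytic enzyme PFKP (at least 106-fold), the fatty acid carrier FABP5 (at least 135-fold) and the carbonic anhydrase CA2 (at least 93.6-fold). LITAF, ADAM19 and RAC2 were at least 60.6-, 77.1- and 60.2-fold higher. The metallothionein MT1E was at least 290-fold higher and the cell cycle inhibitor CDKN1A had a log2 fold change of 6.85 ± 0.28 (SE). In the other direction, the largest differences included 7 probes named for members of the GAGE family. These are cancer-testis antigens encoded by near-identical copies on the X chromosome. The 7 probes were lower in GFP-positive cells, with bounds from at least 94.2-fold for GAGE12B to at least 227-fold for GAGE12C. Other GAGE probes were lower by smaller bounds, among them GAGE2A (at least 65-fold) and GAGE12E (at least 25.4-fold). Probes of GAGE copies can bind one another's transcripts, so which copies differed is uncertain. The imprinted noncoding RNA H19 was at least 130-fold lower, the endothelial-type lipase gene LIPG at least 110-fold, the branched-chain aminotransferase BCAT1 at least 117-fold, the kallikrein KLK11 at least 188-fold, the endoderm transcription factor SOX17 at least 90.9-fold, the aldo-keto reductase AKR1C3 at least 114-fold and the pentraxin NPTX2 at least 105-fold.

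**Figure D1:**
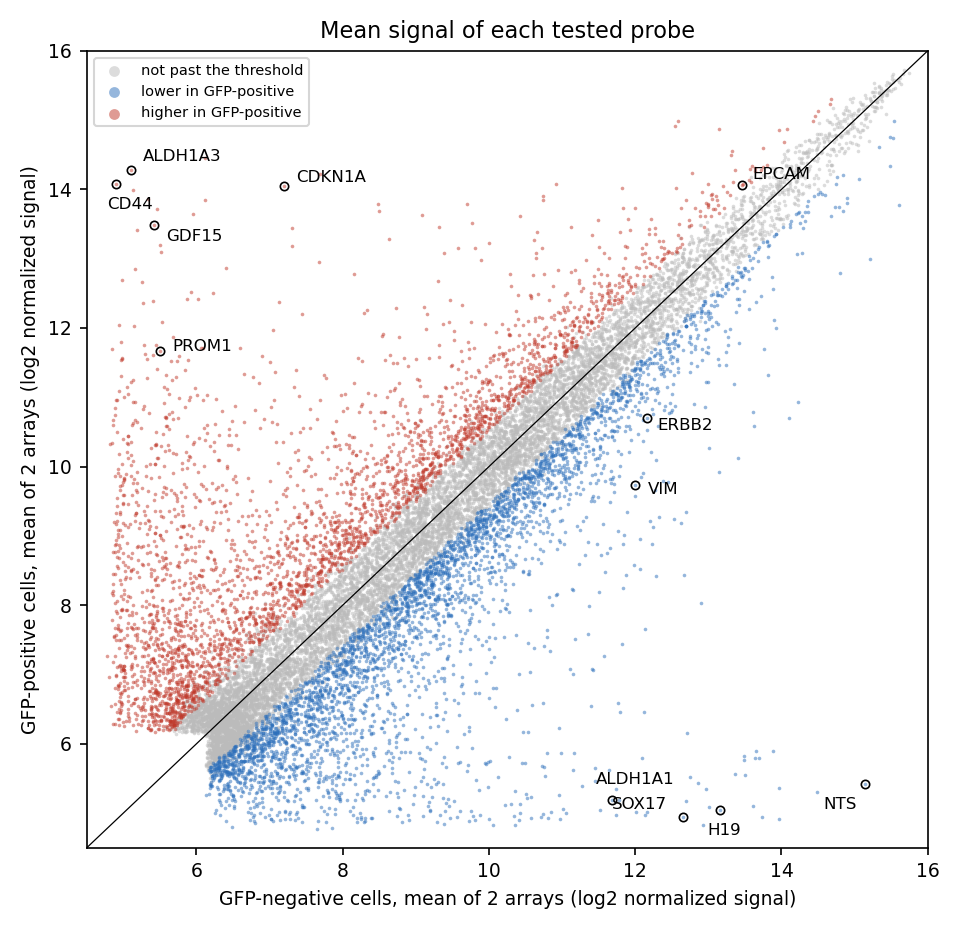
Mean log2 normalized signal of each tested probe in GFP-negative cells (x axis) against GFP-positive cells (y axis), 2 arrays per group, with probes past the adjusted threshold coloured by direction and the line of equal signal drawn. CD44 and ALDH1A3 lie at the upper left, near background in GFP-negative cells, and NTS lies at the lower right at 15.15 against 5.43.

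In all, 7322 of the 18098 tested probes (40.5%) passed an adjusted p of 0.05, 3394 higher and 3928 lower in GFP-positive cells. Which direction held more calls depended on the scaling: 3731 were higher and 3421 lower with cyclic loess, and 3179 and 4466 with 75th percentile scaling. In all 7322 the arrays of the groups did not overlap. They named 5018 of 10955 genes, of which 2356 were higher, 2641 lower and 21 had probes called in both directions. A difference of over 2-fold was seen for 3933 called probes, 2015 higher and 1918 lower. Within the groups, 96 and 260 probes differed by over 2-fold between the GFP-positive and between the GFP-negative arrays. Of the called probes, 1052 were higher and detected on neither GFP-negative array, and 847 were lower and detected on neither GFP-positive array. The bound reached 16-fold for 116 of the first kind and 64 of the second. Leaving out GFP-positive replicate 2 lowered the calls to 4598, with 2292 lower, and leaving out GFP-positive replicate 1 gave 2523 lower. Calls of over 2-fold numbered 2162 without background correction and 2288 in the deposited value table.

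Stem cell markers did not move together. The breast stem cell marker list had 18 tested members, 9 higher, 5 lower and 4 not past the threshold. These counts take no account of whether a high or a low level marks stem-like cells. In breast cancer CD24 is used by its low level, beside high CD44. Besides CD44 and ALDH1A3, the higher members included PROM1, which encodes the surface antigen CD133 (at least 46.8-fold, 11.67 ± 0.06 against 5.50 ± 0.57), the progenitor transcription factor SOX9 (at least 49.8-fold) and CD24 (at least 7.8-fold, 9.09 ± 0.20 against 4.93 ± 0.11), whose other probe was detected on no array. ALDH1A1, a related aldehyde dehydrogenase, went the other way, at least 46.6-fold lower in GFP-positive cells (5.18 ± 0.25 against 11.68 ± 0.59, adjusted p = 3.39e-06). BMI1, NOTCH1, KLF4 and ITGA6 did not pass, with log2 differences of -0.13, -0.12, 0.21 and 0.33. The brightest MYC probe had a log2 difference of 0.55 with an adjusted p of 0.0965, and 0.03 with the replicate pairing as a block. The other tested MYC probe passed in the main comparison (0.69, adjusted p = 0.0408). POU5F1, SOX2, NANOG, ABCG2, ZEB1, ESR1 and CXCR4 were not detected on both arrays of either group and were not tested. As a list, the breast stem cell markers missed the threshold (camera, adjusted p = 0.0968), and passed it at 0.0371 without GFP-positive replicate 2. Of 8 tested pluripotency factors, 2 were higher (DNMT3B among them, log2 fold change 1.15 ± 0.18) and 3 lower: SALL4 at least 7.74-fold, DPPA4 at least 2.21-fold and KLF5 at least 2.6-fold (list adjusted p = 0.544).

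**Figure D2:**
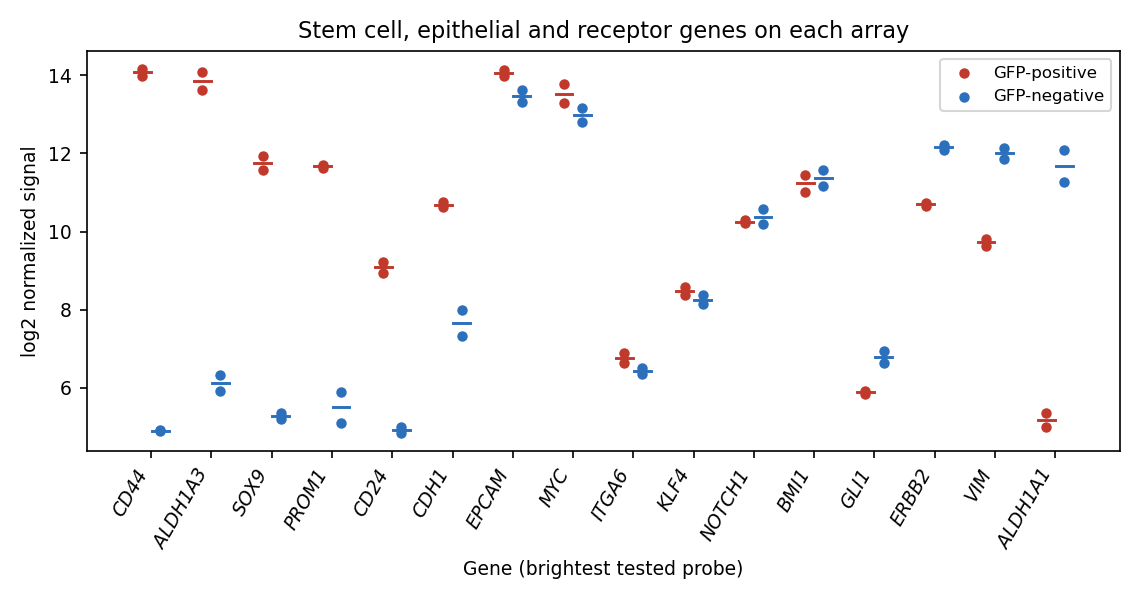
Log2 normalized signal on each array (points) and group means (lines) for the stem cell, epithelial and receptor genes fixed in advance that could be tested, each by its brightest probe, ordered by fold change. CD44 lies at 14.08 in GFP-positive and 4.90 in GFP-negative cells, and ALDH1A1 at 5.18 and 11.68.

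Epithelial adhesion genes were more often higher than lower in GFP-positive cells, and mesenchymal genes were split. Of 21 epithelial members, 10 were higher and 4 lower. The cadherin CDH3 was at least 43.2-fold higher, the cadherin CDH1 and the keratin KRT8 had log2 fold changes of 3.03 ± 0.25 and 5.18 ± 0.34, and the epithelial regulator GRHL2 was at least 8.03-fold higher, while the keratin KRT7 was at least 32.6-fold lower. EPCAM was bright in both groups (14.06 ± 0.12 against 13.46 ± 0.22) and its log2 fold change of 0.60 had an adjusted p of 0.0411, which rose to 0.113 under 75th percentile scaling, 0.0915 without a detection filter, and 0.215, 0.118 and 0.149 without GFP-positive replicate 1, GFP-positive replicate 2 and GFP-negative replicate 1. All 17 tested mesenchymal members passed, 8 higher and 9 lower. CALD1, an actin-binding protein, and the matrix protein SPARC were at least 44.4- and 45-fold higher, while the intermediate filament gene VIM and the actin-binding TAGLN had log2 fold changes of -2.27 ± 0.19 and -4.38 ± 0.52 and the collagen COL5A2 was at least 14.4-fold lower. The mesenchymal list's median was -1.04 and its mean 0.13, with the camera test downwards and fry upwards. Neither list passed as a whole (adjusted p = 0.0968 for epithelial and 0.999 for mesenchymal genes).

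Of 11 tested luminal and apocrine breast markers, 7 were lower in GFP-positive cells, among them the receptor gene ERBB2 (log2 fold change -1.46 ± 0.17, 10.70 ± 0.05 against 12.16 ± 0.09), the adhesion molecule ALCAM (-1.47 ± 0.18) and CLDN8 (at least 1.75-fold). The melanophilin gene MLPH was at least 45.6-fold higher, and the list missed the threshold (adjusted p = 0.0968). Another 21 of the 32 luminal genes with a probe were not detected on both arrays of either group. Basal and myoepithelial markers gave 2 higher, 4 lower and 3 not past: EGFR was at least 9.2-fold higher and the integrin ITGB4 had a log2 fold change of 3.81 ± 0.21, while the laminin LAMB3 had -2.70 ± 0.23 and the keratin KRT5 was at least 1.83-fold lower (list median -0.41, mean 0.14, camera downwards, adjusted p = 0.878).

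Among signalling genes, the growth factor list was shifted towards higher signal in GFP-positive cells, with 14 of 26 members higher and 6 lower (camera, adjusted p = 0.0164). The call ended with probes detected on all arrays only (camera, adjusted p = 0.14) and without GFP-negative replicate 2. With an estimated correlation between genes the adjusted p was 0.566, the lowest of any list in that test. The estimate for the growth factor list was -0.013, below the preset 0.01. Correlation between its genes therefore did not raise the p, and the test's 2 residual degrees of freedom limit it. KITLG, the ligand of the receptor KIT, was at least 84.4-fold higher, the EGFR ligand TGFA at least 11.6-fold higher, and IGFBP2, which binds insulin-like growth factors, had a log2 fold change of 3.91 ± 0.18. Notch pathway genes were split, 4 higher and 6 lower of 17. The Notch effectors HEY1 and HEY2 were lower (at least 85.8-fold for HEY1 and 9.94-fold for HEY2), as was the ligand DLL3 (at least 12.7-fold), and the modifier LFNG was at least 6.95-fold higher. Of 17 Wnt genes, 5 were higher and 2 lower. DKK1, a secreted Wnt inhibitor, and AXIN2, a target of the pathway, had log2 fold changes of 6.53 ± 0.19 and 3.23 ± 0.22. The 4 tested hedgehog genes were all lower, GAS1 at least 18.2-fold and SMO with a log2 fold change of -0.60 ± 0.17, whose adjusted p of 0.0294 rose to 0.0571 with cyclic loess, 0.0534 without a detection filter, and 0.11, 0.177 and 0.0982 without GFP-positive replicate 1, GFP-positive replicate 2 and GFP-negative replicate 1. GLI1, a target of that pathway, was at least 1.56-fold lower (adjusted p = 0.00753, and 0.0544 without GFP-positive replicate 1). In the TGF-beta and BMP list, 6 of 18 were higher, with TGFBR2 at least 17.3-fold, and 9 lower, with SMAD7, ID2 and SMAD6 at -3.41 ± 0.18, -3.40 ± 0.17 and -3.31 ± 0.26. List adjusted p was 0.506 for Notch, 0.359 for Wnt and 0.39 for TGF-beta and BMP.

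Target genes of p53 and immediate early genes gave the lowest list p-values. Of 23 tested p53 targets, 14 were higher in GFP-positive cells and 2 lower (camera, adjusted p = 0.0013, and 0.566 with an estimated correlation between genes). Besides GDF15 and CDKN1A they included PHLDA3, an inhibitor of the kinase AKT, which was at least 6.8-fold higher, and the polyamine enzyme SAT1 (log2 fold change 3.35 ± 0.21). The list's median log2 fold change was 1.11, and 0.90 with members near background set at their bounds. Of 23 immediate early genes, which also respond to cell handling and sorting, 12 were higher and 1 lower (adjusted p = 0.0013, and 0.566 with an estimated correlation). FOSL1 and NR4A2, both transcription factors, were at least 10.8- and 6.98-fold higher, CCN2 at least 7.64-fold higher, and IER3 had a log2 fold change of 3.11 ± 0.17. Of 28 interferon-responsive genes, 14 were higher and 3 lower (adjusted p = 0.0164, 0.566 with an estimated correlation and 0.0582 without GFP-negative replicate 2), with LGALS3BP and HERC5 at least 36.9- and 26.9-fold higher, ISG15 at 4.03 ± 0.23 and BST2 at -3.48 ± 0.17.

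Antigen presentation and inflammatory genes went both ways. HLA-B had a log2 fold change of 4.01 ± 0.17 and HLA-DMA 2.20 ± 0.21, while the immunoproteasome subunit PSMB8 was at least 9.98-fold lower, and the list of 15 had 3 higher and 3 lower (adjusted p = 0.712). Of 17 NF-kB and inflammatory genes, 5 were higher and 4 lower, with the cytokine LIF at 2.29 ± 0.19, the NF-kB inhibitor NFKBIA at -1.63 ± 0.18 and the chemokine CCL20 at least 29.1-fold lower (list median 0.14, mean -0.10, camera upwards, adjusted p = 0.752).

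Metabolic lists showed separate changes within each pathway. Of 18 glycolysis genes, 6 were higher and 1 lower: PFKP as above, and the glucose transporter SLC2A1, the aldolase ALDOC and PFKM at 2.12 ± 0.18, 1.90 ± 0.24 and 1.06 ± 0.18. Of 45 oxidative phosphorylation genes, 1 was higher and 9 lower, with COX6C at -1.06 ± 0.18 and NDUFV1 at -1.01 ± 0.18. Among 24 hypoxia-responsive genes, 10 were higher and 3 lower, with the collagen-modifying enzyme PLOD2 at least 32.1-fold higher and ANGPTL4 at -1.94 ± 0.23. These 3 lists each had an adjusted p of 0.0968. Of 18 cholesterol synthesis genes, 9 were higher, among them EBP (at least 25.2-fold), INSIG1 (1.51 ± 0.25) and MSMO1, and PMVK was lower (-2.16 ± 0.20). That list's adjusted p was 0.0609, and 0.0335 with the replicate pairing as a block. It passed without GFP-positive replicate 2 (0.0371) and without GFP-negative replicate 1 (0.00805), and did not with an estimated correlation (0.612) or without GFP-negative replicate 2 (0.115). Of 24 lipid genes, 10 were higher, including the adipogenic receptor PPARG (at least 23.4-fold) and the lipid droplet protein PLIN2 (at least 27.8-fold), and 7 were lower (adjusted p = 0.222).

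In the aldehyde and NRF2 list, 11 of 27 were higher and 7 lower, with malic enzyme ME1 at least 25-fold higher beside ALDH1A3, and AKR1C3 and ALDH1A1 lower (adjusted p = 0.446). Metallothioneins gave 3 higher and 3 lower of 7: MT1E and MT2A (1.46 ± 0.19) were higher and MT1F (-2.67 ± 0.23) and MT1H (at least 3.77-fold) lower, with a list median of -0.50 and a mean of 0.61 (camera downwards, adjusted p = 0.999). Of 10 drug transporter genes, 5 were higher, with ABCC3 at 4.37 ± 0.28 and MVP at 2.32 ± 0.21, and 2 lower, with ABCA3 at -3.24 ± 0.25 (adjusted p = 0.175; list median 0.77, and 0.41 with members near background at their bounds).

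Of the mitotic, DNA replication and histone genes, more were lower than higher in GFP-positive cells. Most mitotic and DNA replication genes did not pass, however, where 40.5% of all tested probes were called. Of 36 mitotic genes, 8 were lower, including TOP2A (-1.25 ± 0.19), CDCA3 (-1.24 ± 0.21), CENPF (-1.20 ± 0.19) and NEK2 (-1.11 ± 0.19), 1 was higher and 27 did not pass (adjusted p = 0.0968). Of 38 DNA replication genes, 4 were lower, with POLA2 at -1.35 ± 0.23 and RFC3 at -1.03 ± 0.19, and 34 did not pass (adjusted p = 0.752). Histone genes gave 7 lower of 17, H2AC20 and H2AC18 at -2.43 ± 0.23 and -1.99 ± 0.31 among them (adjusted p = 0.126, and 0.0101 without GFP-positive replicate 2). Probes of near-identical histone genes cannot be told apart with certainty. Ribosomal proteins gave 7 higher and 2 lower of 45 (adjusted p = 0.159). The brightest RPL14 probe had -3.05 ± 0.17 while its other tested probe had 0.08. Heat shock genes gave 1 higher and 3 lower of 21, with HSPA4L at -1.46 ± 0.25 and DNAJA1 at -1.14 ± 0.19 (median 0.04, mean -0.08, camera upwards, adjusted p = 0.921). Unfolded protein and ATF4 genes gave 6 higher and 3 lower of 29, with TRIB3 at 3.06 ± 0.24 and ATF3 at 2.68 ± 0.32 (adjusted p = 0.359). Of 27 apoptosis genes, 11 were higher, with BIK at least 8.65-fold, PMAIP1 at 2.31 ± 0.18 and CASP4 at 2.18 ± 0.17, and 5 were lower (adjusted p = 0.104).

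**Figure D3:**
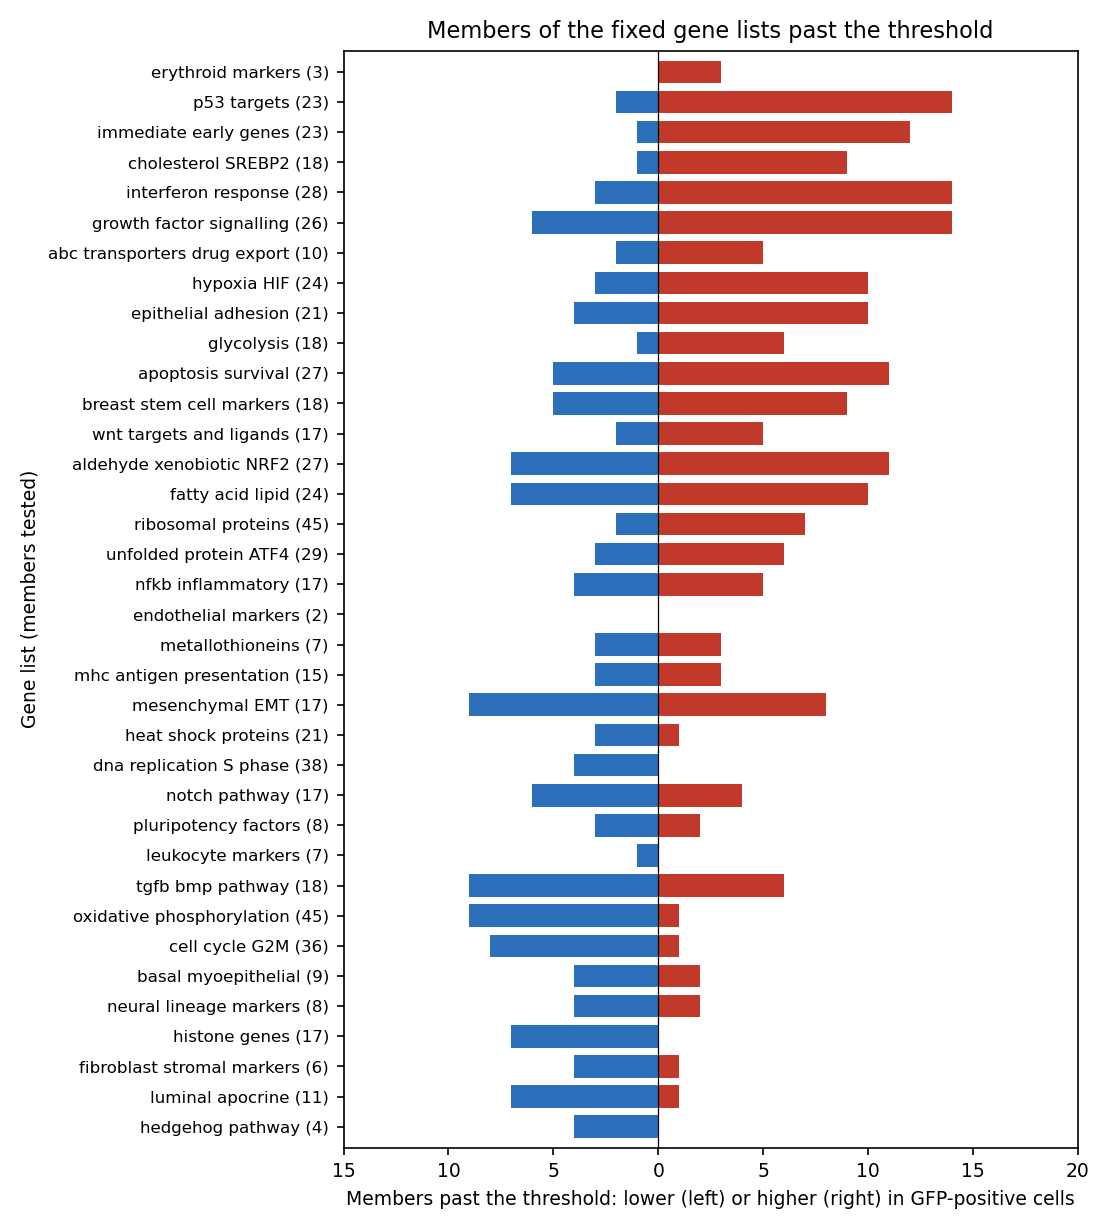
Number of members of each of the 36 fixed gene lists past the adjusted threshold, higher in GFP-positive cells to the right and lower to the left, with the number of members tested in brackets. The p53 target list shows 14 higher and 2 lower of 23, and the luminal list 1 higher and 7 lower of 11.

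Markers of other cell types were few. Leukocyte markers gave 1 lower (CD79B, at least 2.17-fold) and 6 not past of 7, and neither of the 2 tested endothelial markers passed (ESAM -0.40, CD34 -0.28). Fibroblast markers gave 1 higher (ACTA2, at least 13.5-fold) and 4 lower of 6, including the collagens COL3A1 (at least 5.92-fold) and COL1A2 (at least 3.95-fold). Neural markers gave 2 higher, TUBB3 (3.93 ± 0.18) and SCG2 (at least 18.4-fold), and 4 lower, among them NES (-4.33 ± 0.19) and OLIG2 (at least 7.86-fold), of 8. The 3 tested erythroid genes were higher in GFP-positive cells: HBG1 at least 4.89-fold, HBG2 with a log2 fold change of 2.52 ± 0.17 and HBA2 at least 1.92-fold (adjusted p = 0.00937, and 0.0761 without GFP-positive replicate 2). HBG1 and HBG2 are near-identical and their probes may not separate them. List adjusted p was 0.545 for leukocyte, 0.207 for fibroblast and 0.359 for neural markers.

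Counts of list members above use p adjusted over all tested probes. Adjusted over the list alone, the number past the threshold rose from 14 to 15 for epithelial, 8 to 10 for luminal, 7 to 8 for Wnt, 16 to 17 for p53, 13 to 14 for hypoxia, 17 to 20 for lipid, 18 to 19 for aldehyde and NRF2, 20 to 22 for growth factor and 5 to 6 for fibroblast genes. It fell from 4 to 3 for DNA replication, 4 to 3 for heat shock and 10 to 6 for oxidative phosphorylation genes, and was equal for the other 24 lists.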

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

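The settings named here were planned, except the list medians at bounds, the folds of genes detected on 1 array of the dimmer group, the cell type markers counted by any 1 probe and the chromosome test with an estimated correlation, which were chosen after seeing the data. No called probe changed sign under any setting that tested it. All 7322 calls were shared with the replicate block, which gave 8471. Of 159 named probes past the threshold, 147 stayed past it under every alternative that tested them. MYC gained a call without background correction, in the deposited table, with the block and with the intensity trend (adjusted p from 0.0153 to 0.0396). With an array left out, BMI1 ranged from -0.348 to 0.078, changing sign without GFP-positive replicate 1 and (0.077) without GFP-negative replicate 2, and NOTCH1 from -0.314 to 0.064, changing sign without GFP-negative replicate 1, none of them called. Besides MYC and the cholesterol list, the block changed no other call of a named gene or a list. Signal over background limits the folds of dim probes.

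Requiring detection on all arrays gave fewer tested probes and 4789 calls, 2065 higher, 1504 genes higher and 1902 calls of over 2-fold. Calls of over 2-fold numbered 2162 without background correction and 2288 in the deposited table, where folds are compressed by background left in. Leaving out 1 array gave 4598 to 7110 probes called, 2292 to 3788 lower, 3250 to 4882 genes called and 1609 to 2523 genes lower, from fewer arrays.

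For the gene lists the values are adjusted p, and the causes were not tested. Lists past the threshold numbered 4, and 13 without a detection filter, 7 with detection on all arrays, 20 with fry, 0 with an estimated correlation and 2 to 8 with an array left out. With an estimated correlation, p53, interferon, immediate early and growth factor lists were each at 0.566, the lowest value of any list. On 2 residual degrees of freedom that setting cannot decide which lists hold. Without a detection filter, lists newly past were epithelial and hypoxia (0.0417 each), mitotic (0.025), histone and ribosomal (0.0376 each), glycolysis (0.027), oxidative phosphorylation and cholesterol (0.0164 each), and erythroid (0.0436), which had too few members to be tested in the main comparison. The erythroid list also had enough members without GFP-positive replicate 2 (0.0371) and without GFP-negative replicate 2 (0.177). With detection on all arrays, newly past were mesenchymal (0.0256), luminal (0.0433), cholesterol (0.0293) and apoptosis (0.0256), growth factor was lost (0.14), and pluripotency (0.181), breast stem cell (0.362) and Notch (0.806) reversed. Cholesterol also passed without background correction (0.0424), with an offset of 50 (0.0491), in the deposited table (0.0414), with the replicate block (0.0335) and with probe means (0.0394), and the breast stem cell list passed with probe means (0.0394). Over all its alternatives the cholesterol list ranged from 0.00805 to 0.612.

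With fry, which does not compare a list with other genes, newly past were pluripotency, epithelial, Wnt, apoptosis and fibroblast (0.0143 each), breast stem cell (0.00103), Notch (0.0393), TGF-beta (0.0295), drug transporters (0.0308), hypoxia (0.0122), glycolysis (0.0103), oxidative phosphorylation (0.015), lipid (0.00367), ribosomal (0.0485) and leukocyte (0.0338), and mesenchymal (0.154), basal (0.15), heat shock (0.81) and metallothionein (0.0395) reversed. Lists without a call also reversed elsewhere: mesenchymal (0.842), heat shock (0.83) and metallothionein (0.905) under 75th percentile scaling, metallothionein without background correction (0.98), with an offset of 50 (0.968), without a detection filter (0.973) and in the deposited table (0.985), and heat shock (0.986) and leukocyte (0.977) with probe means. With an array left out, the ranges were 0.0371 to 0.115 for breast stem cell, 0.842 to 0.975 for mesenchymal, 0.161 to 0.87 for DNA replication, 0.0101 to 0.356 for histone, 0.0181 to 0.0582 for interferon, 0.756 to 0.906 for heat shock, 0.00805 to 0.115 for cholesterol, 0.842 to 0.9998 for metallothionein and 0.00737 to 0.0683 for growth factor lists. Directions reversed for mesenchymal without either GFP-positive array or GFP-negative replicate 2, for DNA replication without GFP-positive replicate 2, and for heat shock and metallothionein without GFP-positive replicate 2 or GFP-negative replicate 1. The growth factor and interferon lists lost the call without GFP-negative replicate 2.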

Other observations

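The 10 lists reported here first (germline, imprinted and those of the next paragraph), the normalization test, the array sensitivity test, the count of cell type markers by any 1 probe and the stem marker probe test were chosen only after the results were seen, erythroid cells were set apart from the other cell types after their values were seen, and the genes of these lists were named after their values were seen. Germline and cancer-testis genes went both ways: of 46 with a probe, 13 were lower in GFP-positive cells and 7 higher. Most of the lower ones are GAGE copies, whose probes can bind one another's transcripts, and several of the higher ones belong to the MAGEA family. These counts are therefore not of independent genes. Beside the GAGE probes, the pluripotency-associated DPPA2 was at least 48.2-fold lower and the germ cell genes YBX2 and CCNA1 at least 23.9- and 23.8-fold lower. MAGEB2 (5.88), MAGEA3 (at least 7.03-fold), GTSF1 (6.45) and PRAME were higher. Of 23 imprinted genes with a probe, 5 were higher and 4 lower. All 3 SNRPN probes were lower, the strongest at least 28.4-fold, as were both ZNF331 probes, while both GRB10 probes (at least 8.15-fold for the stronger), SGCE (3.76) and PHLDA2 (2.86) were higher. GSTT1, a glutathione transferase, was at least 15.8-fold lower.

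Of 15 Müllerian tract genes with a probe, 6 were higher, with MSLN at least 30.4-fold and KLK6 at 4.63, and 5 lower, with SOX17 and WT1 among them. Of the intestinal genes 2 of 18 were higher (AXIN2, and PPP1R1B at least 1.8-fold), of prostate genes 1 of 7 (SLC45A3, 2.65) and of kidney genes 1 of 5 (PAX8, at least 1.24-fold), while 2 of 8 squamous genes were lower (KRT5, and SPRR1A at -0.56). No melanocyte or lung gene, of 7 each with a probe, was detected on both arrays of either group, so none was tested, and the 1 tested liver gene of 9, APOA1, did not pass (-0.33, unadjusted p = 0.126, limma). By position, camera called 0 of 23 chromosomes with a preset or an estimated correlation. At an unadjusted p under 0.05 there were 3 and 2, and the lowest adjusted p was 0.273 with the preset correlation. The estimated version rests on 2 residual degrees of freedom, so its 0 calls add little.

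About 2 in 5 tested probes differed between the GFP groups, many from background to high signal. Whether this gap is wide for fractions of 1 line was not tested, since no other fractions or lines were compared. Normalization is argued against for the number of calls, since 5 other scalings called at least 7152 probes. The size of the differences did depend on processing. Calls of over 2-fold fell from 3933 to 2162 without background correction and to 2288 in the deposited table. Leukocytes, fibroblasts or endothelial cells passing with a gate are argued against too, with at most 5% of a type's markers detected on both arrays of a group and, over all probes of the gene, on none of the other. Counting a gene by any 1 of its probes, the share was 6.25% for fibroblasts, from COL1A2, and unchanged for leukocytes and endothelial cells, still under the bound set for this outcome. The collagens COL3A1, COL1A2 and COL1A1 were lower in GFP-positive cells (8.80, 8.12 and 7.39 in GFP-negative cells), and fry gave the fibroblast list 0.0143, while COL1A1 lost its call without a detection filter (0.126), without GFP-positive replicate 2 (0.177, log2 fold change -0.63) and without GFP-negative replicate 1 (0.167, -0.81). FBLN1 was lower too on its 3 called probes (8.66 against 10.67, 9.46 against 10.11 and 6.39 against 7.55), as was 1 of 2 S100A4 probes (9.63 against 10.47), and the other S100A4 probe did not pass (14.22 against 14.67). Even so, the fibroblast transcripts DCN and LUM were detected on no array and ACTA2 went the other way. For erythroid cells the share was 11.1% (1 of 9), or 22.2% by any 1 probe, between the bounds set for either outcome, and HBB lay near background in both groups (5.94 and 6.14) and ALAS2 was detected on no array, while HBG1 and HBG2 were higher (8.41 and 8.68), so this stays open. Copy number may add a part: after chromosome medians were removed, fold changes of genes 5 to 20 Mb apart correlated at 0.0108, above the highest of 1000 shuffles (0.00753), with a covariance of 0.0188 against 0.000781 from replicate noise. The difference between the GFP-negative replicates correlated more, at 0.0242, and at 20 to 50 Mb the group value (0.00478) was reached by 94 shuffles. Shared regulation of neighbouring genes was not tested. Within 1 Mb the group value was 0.0615 and that of the GFP-negative replicates 0.108. A difference between stem-like and other cells stays open as well.

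Many luminal breast markers lay near background in both groups, with 21 of 32 detected on both arrays of neither, GATA3, PIP, TFF1, APOD and SCGB2A2 among them, although FOXA1 (8.14 and 9.08), ERBB3 (8.81 and 9.66), XBP1, ALCAM, FKBP5 and ERBB2 were detected on all 4 arrays and TRPS1 on 3. Low sensitivity for the missing genes stays open: 84% of epithelial adhesion genes were detected on both arrays of at least 1 group, but these are another class of genes, so their share does not decide it. Intestinal cells in the GFP-positive group are argued against, with 1 of 16 markers outside the earlier lists higher there. That covers 1 lineage in 1 group, and other lineages and the GFP-negative group were not tested in this way. Of 15 Müllerian genes with a probe, 9 were detected on both GFP-negative arrays and 8 on both GFP-positive arrays. MUC16 of that list was at least 3.09-fold lower in GFP-positive cells. Whether the cultures of either group had drifted from the labelled line could not be tested, since no reference profile of the line was used here. It was likewise not tested whether both groups held cells of the same line.

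Stem cell markers split, with CD44, ALDH1A3, PROM1 and SOX9 higher and ALDH1A1 lower in GFP-positive cells. CD24, used as a marker by its low level, was higher as well. A single misleading probe (the explanation that 1 probe per gene decides the direction) is argued against only for the markers with several called probes. Of these markers, 0 had called probes in opposite directions. CD44 had 3 called probes, with bounds from 1.6- to 248-fold, and ALDH1A1 and ALDH1A3 had 2 each. PROM1, SOX9 and CD24 rest on 1 probe, and the other CD24 probe was detected on no array and lay level (5.64 and 5.74).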
